A study of Rattus norvegicus with 9 samples.

How the data were processed

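Values in FPKM (fragments scaled to transcript length and to the number of mapped fragments) for 18843 gene symbols and 9 tibia libraries were taken from 1 table the authors deposited for the whole series. Library columns were matched to samples by the sample names in the labels, and 0 columns were left unused. RNA was prepared, per the labels' protocols, by acid phenol and chloroform extraction, filter columns and DNase digestion. The submitters' processing notes name DESeq2, without a version, and R 3.2.0. The aligner, the counting program and the genome build are not given in the sources used here. The series design text speaks of a microarray while its type and the deposited FPKM values are those of sequencing, and the values were treated as sequencing data.

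FPKM values are not read counts, so no count model was used. Low values were checked for whole-read steps. Genes were taken whose values lay above 0 and under 0.15 both in a library and in Model replicate 1. Of the ratios between these values, 76.6% to 78.6% lay within 0.01 (log2) of a ratio of whole numbers up to 6, against 8.52% for random ratios. The steps gave relative depths of 94.8% to 101% of Model replicate 1. FPKM sums ran from 448643 to 504125 per library and differ because the unit does not fix them. Precision was taken from the spread between libraries alone.

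Groups (Model, PH and PPH, 3 libraries each) come from the treatment named in the labels. Genes with a mean of at least 1 FPKM over the 9 libraries were tested, 12424 in all, and 488 genes were at 0 in every library. Values were taken as log2(FPKM + 1), so that fold changes of low genes are understated. One limma fit (limma 3.58.1 in R 4.3.3, empirical Bayes with a trend) held a mean per group, and the 3 comparisons were PPH against Model, PPH against PH and PH against Model, two-sided. P-values were adjusted by the method of Benjamini and Hochberg, and 0.05 was the threshold. A gene was called separated when all 3 libraries of one group lay above all 3 of the other, which chance gives for 10% of genes.

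The gene lists, 28 in number, covered bone cells, repair matrix, signalling, blood and immune cells, muscle, fat, nerve, metal handling, stress and general cell functions, and were fixed before the data were examined, as were the main test and the alternatives named in the last paragraph, with the exceptions given there. Of these, 27 had tested members, and the list of mitochondrially encoded genes had 0 in the table. Lists were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other genes, and beside it with camera at an estimated correlation and with fry. The fry p tests whether the genes of a list move, on balance, one way, and compares the list with no other genes; its mixed p tests whether they move in either direction. The ribosomal list, taken by a rule on symbols, also held 8 tested S6 kinase genes and Rps19bp1, and was tested again without them. Members were also adjusted over the list alone. The 3 added lists (small intestine, eosinophil and mast cell, and MHC class I genes with Fam111a) were written after the values were seen. Some genes stand in more than 1 list.

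Named genes follow a rule fixed in advance. Per comparison it takes the genes past the threshold with separated groups, up to 10 in each direction. Where fewer than 5 pass in a direction, the genes with the smallest p fill it up to 5 and are said not to pass. It adds up to 4 members with the smallest p of each list and 14 bone genes. Genes outside the rule are said to be chosen after their values were seen. Symbols were matched without regard to case and then by RefSeq synonyms of the GRCr8 assembly table, where 16899 symbols were found directly and 523 as synonyms. No coordinates are given, since the build of the files is not stated. Defensin, globin, ribosomal protein and MHC class I genes have near-identical copies, and how reads shared between copies were counted is not given in the sources used here.

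The test was checked on 20 simulated runs of PPH against Model over 12424 genes with the spread of these libraries. Of 200 changed genes per run it recovered 89.3% of those with a 2-fold change and 98.9% with a 4-fold change, with 9.3 false calls per run. A list of 30 genes moved by 0.5 (log2) was found by camera in 20 of 20 runs and an unmoved one in 0. The simulated genes varied independently, unlike those of a tissue. With 200 changed genes per run the adjustment is milder than where few genes change. The recovered shares therefore do not apply to comparisons with few calls, where changes of these sizes can be missed. In PH against Model, Pcyt1b had a log2 fold change of 1.31 and a limma adjusted p of 0.166.

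Alternatives were pseudocounts of 0.1 and 0.01, no filter and a filter at a mean of 5 FPKM, median-ratio scaling, quantile normalization, equal sums (TPM), robust and untrended empirical Bayes, library weights, only the 2 groups compared, a replicate block, and each library left out in turn. Leaving out the intestinal genes, taking the S6 kinases and Rps19bp1 out of the ribosomal list, and testing the fibrous list with fry under the other settings, were added after the data were seen. Splits of the libraries were refitted, all 10 per comparison of 6 libraries and 100 of the 280 splits of all 9. The real groups were among the splits each time, and the rest of the 100 were drawn at random. Fold changes of comparisons that share the Model libraries were set beside 100 simulations of unchanged groups. The simulated groups and their shared control were drawn from the deviations of all 9 libraries from their group means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.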

Results

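Gene expression was measured by RNA sequencing in the tibia of male Sprague Dawley rats, an outbred laboratory stock, that were 10 weeks old and carried a bone defect. Bones were harvested at week 2 from 3 groups with 3 libraries each. The Model group (replicates 1, 4 and 5) was left untreated. The PH group (replicates 2, 3 and 4) received a peptide hydrogel, a water-rich gel built from short peptides. The PPH group (replicates 2, 3 and 4) received a hydrogel with processed pyritum, a mineral of iron disulfide used in traditional medicine. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The table held 18843 gene symbols, which are the only identifiers given, with 16784 to 16953 of them above 0 in a library. Globin genes took 11.5% (PPH replicate 4) to 20.3% (PH replicate 4) of the summed FPKM, and Spearman's rho between libraries across genes ran from 0.981 to 0.99. Low values stood in whole-read steps, which put the relative depth of the libraries at 94.8% to 101% of that of Model replicate 1. The absolute depth is unknown.

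PPH was set against Model to ask which transcripts differ in the tibia when the defect holds the mineral hydrogel, and only Defal1, a defensin gene, passed the limma test over 12424 genes. Defal1 stood at an FPKM of 24.2 ± 1.74 in PPH and 13.4 ± 0.751 in Model (SD, n = 3 each), a log2 fold change of 0.80 ± 0.08 (SE) with a limma adjusted p of 0.0262. The next transcripts in order of p, none past the threshold, were Pcyt1b (an enzyme of phosphatidylcholine synthesis, log2 fold change 1.09), the Paneth cell defensin Defa9 (0.73), Itln1 (intelectin, 0.58) and Crabp2 (a retinoic acid binding protein, 0.76). Of those lower in PPH, also without passing, RT1-A2 (MHC class I) had a log2 fold change of -1.35. The circadian clock genes Per1 (-0.87) and Per2 (-0.46), the histone gene hist1h2ail2 (-0.63) and Clec2l (-0.70) followed it. At an unadjusted p under 0.05 limma counted 278 genes higher and 131 lower, 409 in all, where 621 would be expected by chance if no gene differed. Genes that vary together widen the range of such a count. The count of 1 became 0 without Model replicate 4 or 5, PH replicate 2 or 4, or PPH replicate 2, and 3 without Model replicate 1 or PH replicate 3. Without PPH replicate 4 another gene, lower in PPH, was the 1 called.

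The 14 bone genes chosen in advance did not pass the limma test between PPH and Model. Runx2 (log2 fold change 0.07 ± 0.12 SE) and Sp7 (0.06 ± 0.20), transcription factors of osteoblasts, and the mineralisation enzyme Alpl (0.04 ± 0.19) lay close to 0. The matrix genes Col1a1 (-0.03), Bglap (0.20), Spp1 (0.14) and Ibsp (0.31) and the osteoclast genes Acp5 (0.05) and Ctsk (0.09) also stayed short of the threshold. The signals Bmp2 (-0.20), Vegfa (0.22), Tnfsf11 (0.14), Tnfrsf11b (-0.06) and Sost (0.17) did so too. In all, 11 of the 14 were higher in PPH and 3 lower, 0 at an unadjusted limma p under 0.05, and the smallest adjusted p was 0.986. In PPH replicate 3 the level of Col1a1 was 13619 FPKM, against 8729 and 8404 in PPH replicates 2 and 4. With quantile normalization Bglap and Acp5 were lower in PPH (-0.09 and -0.07) and Col1a1 higher (0.155). That normalization sets each value by the rank of the gene within its library.

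**Figure D1:**
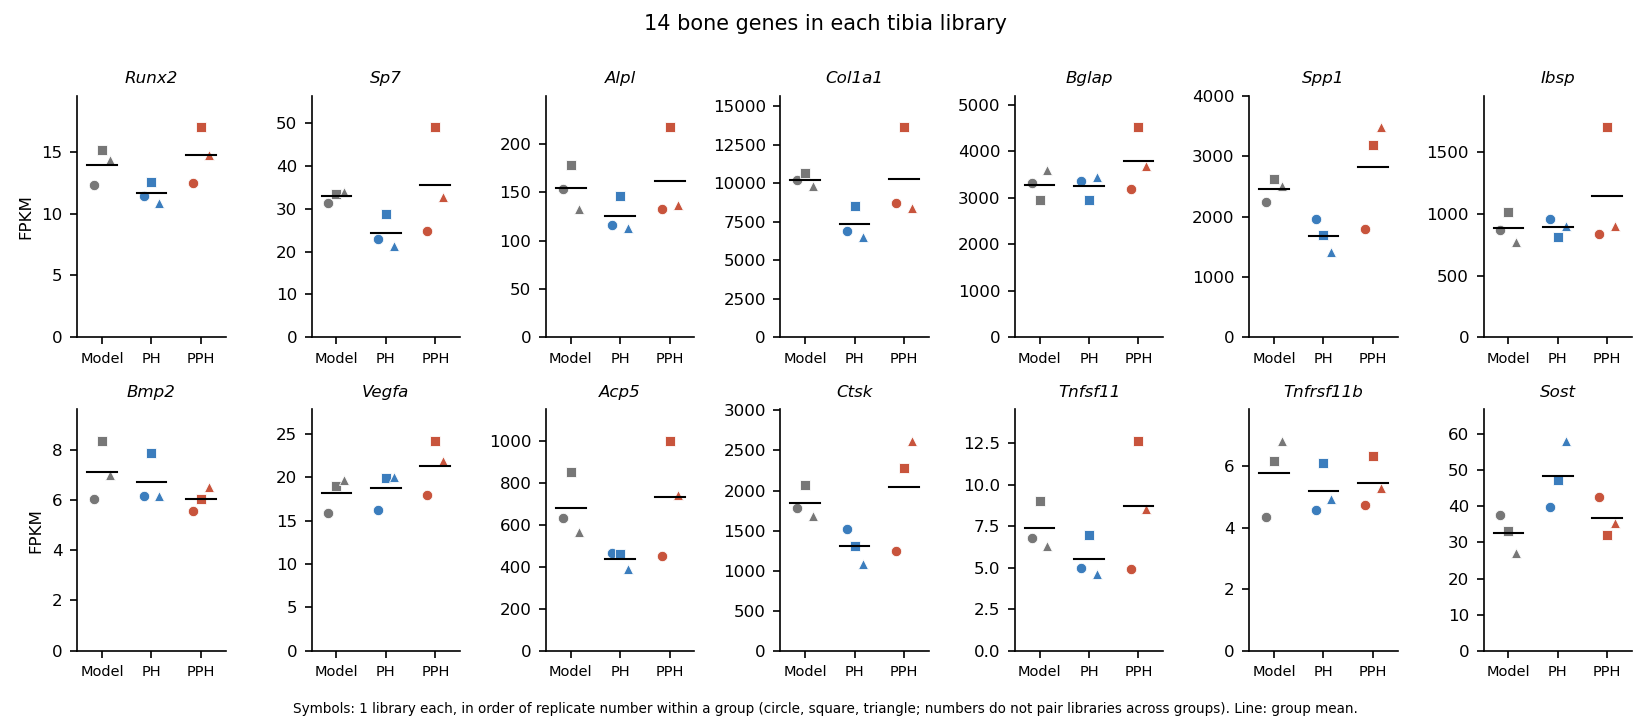
FPKM (linear axis from 0) of 14 bone genes in each library of the Model, PH and PPH groups; each symbol is 1 library and each line the mean of 3. For genes such as Runx2, Sp7, Alpl and Col1a1, PPH replicate 3 (square) lies above the other PPH libraries, which lie below the highest Model library.

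Among the 27 gene lists tested, the fibrous repair matrix list (collagens, matrix proteins and fibroblast genes) had the smallest camera p in PPH against Model. 29 of its 30 members were higher in PPH, with a median log2 difference of 0.27 and a camera adjusted p of 1.39e-11 (adjusted p = 0.516 with an estimated correlation). Its leading members were Col6a1 (log2 fold change 0.38), Col6a2 (0.39), Col3a1 (0.46) and Tagln (0.40), and 0 of the 30 passed limma either over all genes or adjusted over the list alone. The ribosomal list (86 of 101 higher, median 0.10, adjusted p = 3.8e-09) and nuclear genes of the mitochondrial respiratory chain (29 of 34, median 0.07, adjusted p = 0.000634) were also called higher by camera. With an estimated correlation the adjusted p = 0.714 for both. The ribosomal list was set by a rule on symbols that also took 8 S6 kinase genes and Rps19bp1, which encode no ribosomal proteins, and without these 9 it had 84 of 92 genes higher (median 0.105, camera adjusted p = 6.56e-11, estimated-correlation adjusted p = 0.714). Wnt signalling (24 of 34, median 0.14), osteocyte (12 of 12, 0.13), interferon response (19 of 27, 0.14) and growth factor genes (18 of 24, 0.07) were called higher too, as were endothelium (20 of 25, 0.08) and BMP and TGF-beta signalling genes (21 of 31, 0.05). For these 6 lists the camera adjusted p lay between 0.00357 (Wnt signalling) and 0.0405 (endothelium), and again adjusted p = 0.714 with an estimated correlation. The osteoblast list (17 of 22 higher, median 0.07, camera adjusted p = 0.0403) had adjusted p = 0.772 with an estimated correlation.

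Lists called lower by camera in PPH against Model held blood, muscle and dividing cell genes. Proliferation genes such as Bub1b (log2 fold change -0.24) were lower in 30 of 32 cases (median -0.13, camera adjusted p = 1.12e-05), and B cell genes such as Blk (-0.62) in 18 of 20 (median -0.29, adjusted p = 4.05e-05), and for both adjusted p = 0.714 with an estimated correlation. Skeletal muscle (17 of 21 lower, median -0.38, camera adjusted p = 0.00555) and erythroid genes (23 of 26, median -0.14, adjusted p = 0.00555) followed, then T and NK cell genes (19 of 23, median -0.13, adjusted p = 0.0281). With an estimated correlation the adjusted p = 0.714 for muscle, 0.76 for erythroid and 0.743 for T and NK cell genes. In none of the 27 lists did a member pass limma adjusted over the list alone, and fry called 0 lists (lowest adjusted p = 0.854). The other 12 lists were not called by camera. They were osteoclast (median 0.05), cartilage (-0.07), hypoxia (0.03), neutrophil (-0.02), cytokine (-0.11), megakaryocyte (0.13), adipocyte (-0.10), nerve (0.02), iron and metal handling (0.02), oxidative stress (0.02) and immediate-early genes (-0.02), and monocyte and macrophage genes, whose median (0.000357) and mean (-0.02) differ in sign.

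Single libraries moved the 15 list calls. Without PPH replicate 3 there were 7, the osteoblast list was lower in PPH (median -0.15, camera adjusted p = 4.13e-05), and calls ended for the osteocyte (median 0.01), Wnt (0.07), BMP (0.02), growth factor (-0.000144), endothelium (0.01), interferon (0.03), B cell (-0.06), T cell (0.01) and proliferation lists (-0.02). Without Model replicate 1 calls ended for the osteoblast (0.03), growth factor (0.06), endothelium (0.07), interferon (0.05), Wnt (0.09), erythroid (-0.085) and T cell lists (-0.08). Without Model replicate 5 they ended for the osteoblast (0.07), growth factor (0.07), endothelium (0.01), interferon (0.04), BMP (0.03) and muscle lists (0.09, the sign turned). The T cell call also ended without Model replicate 4 (-0.09) or PPH replicate 2 (-0.12), the muscle call without PPH replicate 2 (-0.23) and the erythroid call without PPH replicate 4 (-0.01). Fibrous, ribosomal and respiratory chain calls held without each of the 9 libraries in turn, with medians of 0.21 to 0.31, 0.05 to 0.14 and 0.01 to 0.09. Some medians moved by over 1.5 times while the call held. Without PPH replicate 2 they were 0.26 for osteoblast, 0.24 for osteocyte, 0.13 for BMP, 0.12 for growth factor, 0.13 for endothelium, -0.26 for erythroid and -0.21 for proliferation genes. Without Model replicate 4 they were 0.13 for osteoblast, 0.08 for BMP, 0.155 for growth factor, 0.13 for endothelium, 0.265 for interferon, -0.60 for muscle genes and 0.06 for the ribosomal list. Without PPH replicate 4 they were 0.12 for osteoblast, -0.50 for B cell, -0.30 for T cell and 0.01 for respiratory chain genes and 0.05 for the ribosomal list, and without Model replicate 5 0.07 for Wnt and -0.20 for T cell genes. Lists not called with all libraries were called by camera without PPH replicate 2 (osteoclast 0.15, neutrophil -0.33, cartilage -0.21 and megakaryocyte -0.18), PPH replicate 3 (megakaryocyte 0.355) and Model replicate 1 (cartilage and adipocyte, both -0.25). They were called also without Model replicate 4 (neutrophil -0.12), Model replicate 5 (cytokine -0.13) and PPH replicate 4 (cytokine -0.215, megakaryocyte 0.25, adipocyte -0.27, cartilage 0.05, oxidative stress 0.04 and hypoxia 0.02). With median-ratio scaling 6 lists were called higher and 5 lower, against 10 and 5 as deposited, and with library weights 8 were called.

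**Figure D2:**
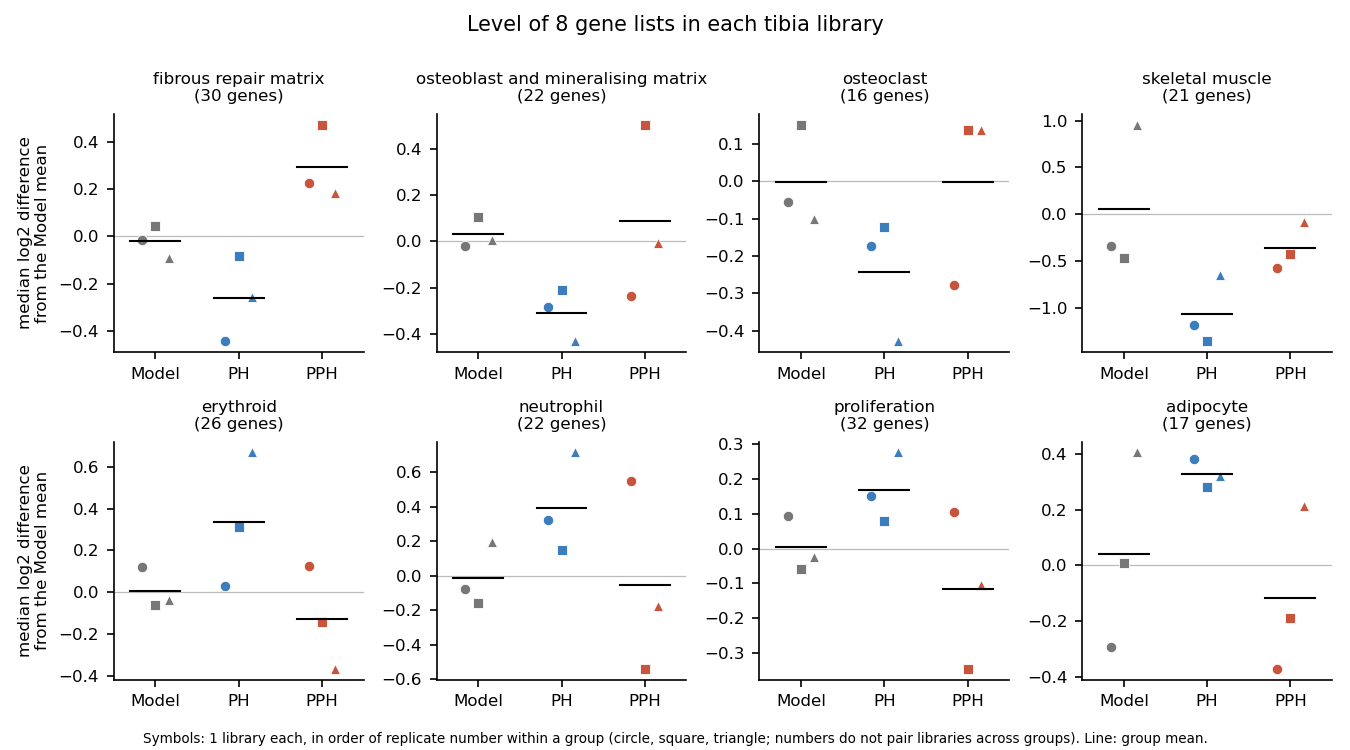
Level of 8 gene lists in each library, as the median over members of the log2 difference from the Model mean (vertical axis, own scale per panel); each symbol is 1 library and each line a group mean. All 3 PPH libraries lie above all 3 PH libraries in 2 of these 8 lists, fibrous repair matrix and skeletal muscle; in the osteoblast list PPH replicate 3 stands at 0.50 and PPH replicate 2 at -0.24.

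PPH was compared with PH to ask what differs with the mineral component, and 5 genes rose in PPH while 0 fell (limma over 12424 genes). A batch that follows the groups cannot be told apart from the treatment in any of the comparisons, because the labels give no batch. Defal1 rose by a log2 of 1.00 ± 0.08 (SE, adjusted p = 0.00344), from an FPKM of 11.6 ± 0.556 in PH to 24.2 ± 1.74 in PPH (SD, n = 3 each, limma). Defa9 (1.00 ± 0.11) and Defa24 (0.98 ± 0.12), defensins of the Paneth cells of the small intestine, rose with it at limma adjusted p of 0.0165 and 0.0201. The other genes were Krt8, a keratin of simple epithelia (0.79 ± 0.09, limma adjusted p = 0.0165), and Tff3, the trefoil peptide of goblet cells (0.97 ± 0.12, limma adjusted p = 0.0201). All 5 were higher in each of the 3 PPH libraries than in any PH library, and all are genes of intestinal epithelium, a tissue the labels do not mention. Lower in PPH without passing were Cd163, a macrophage scavenger receptor (log2 fold change -0.70, limma adjusted p = 0.0824), and the detoxification enzymes Fmo2 (-0.79) and Sult1a1 (-1.06), followed by Plcl2 (-0.56) and Tinagl1 (-0.62).

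Of a list of 33 small intestine genes written after these values were seen, 24 had a mean of at least 1 FPKM and were tested. These 24 were all higher in PPH than in PH, at a median of 1.96-fold, and the other listed genes were not tested. All 24 passed limma adjusted over the list alone, which is no independent evidence, because the list was prompted by the same libraries. Chosen after their values were seen, examples were the enterocyte genes Fabp1 (log2 fold change 1.44), Fabp2 (1.62) and Vil1 (0.87) and the goblet cell genes Zg16 (1.28) and Clca1 (0.66). Each of the 24 was above 0 in every Model library, and PPH was 1.39-fold and PH 0.73-fold of Model at the median. At an unadjusted p under 0.05 limma counted 1038 genes higher and 909 lower in PPH than in PH, 1947 in all against 621 expected if no gene differed, but another split of the same 6 libraries gave 1891. The groups were fully separated for 15.7% of genes, against 18.1% between PH and Model and 7.86% between PPH and Model, where chance gives 10%. The count of 5 was 1 without PPH replicate 3, 2 without Model replicate 5, 9 without PH replicate 3, 13 without PH replicate 4 and 15 without Model replicate 1. Without PPH replicate 2 it was 1004, with 556 genes higher and 448 lower, among them the 5. Without PPH replicate 4, 2 genes were higher and 2 lower, and 1 of these 4 was among the 5. Near-identical defensin copies can share reads, so the level of a single defensin gene is uncertain.

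**Figure D3:**
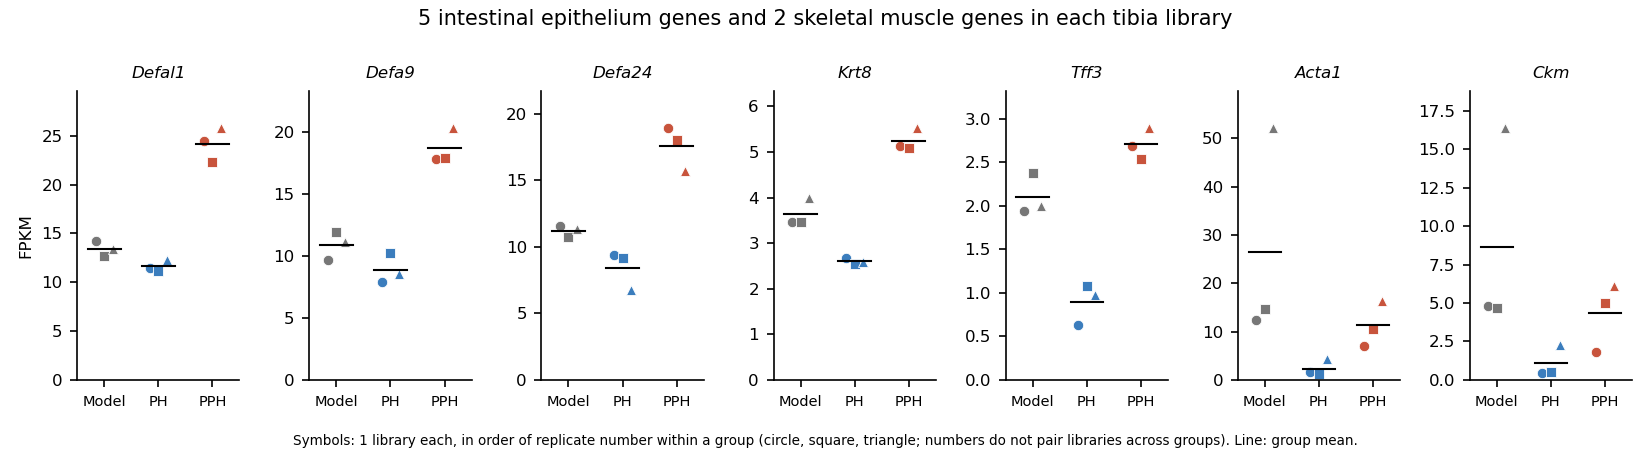
FPKM (linear axis from 0) of 5 intestinal epithelium genes (Defal1, Defa9, Defa24, Krt8, Tff3) and 2 skeletal muscle genes (Acta1, Ckm) in each library; each symbol is 1 library and each line the mean of 3. The PPH libraries lie above all others for the 5 intestinal genes, and Model replicate 5 (triangle) stands apart for Acta1 at 52.1 FPKM.

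Of the 27 lists fixed in advance, fibrous repair matrix had the smallest camera p between PPH and PH. All 30 members were higher in PPH, at a median log2 difference of 0.58, and 23 of them rose when adjusted over the list alone, although 0 passed over all genes (limma). The leading members were Mfap4, a microfibril protein (log2 fold change 2.00 ± 0.34 SE), Col3a1, the collagen of early repair tissue (0.97 ± 0.17), Col6a1 (0.67 ± 0.13) and the matrix protease Mmp2 (0.66 ± 0.13). Col3a1 stood at 480.4 ± 57.1 FPKM in PPH, 249 ± 60.4 in PH and 348 ± 32.8 in Model (SD, n = 3 each). Postn (1.17 ± 0.24) and the myofibroblast gene Acta2 (0.74 ± 0.18), named after their values were seen, were also among the 23. Camera called the list higher (adjusted p = 4.33e-22), with adjusted p = 0.123 with an estimated correlation, and fry in 1 direction called it alone of the 27 (adjusted p = 0.0219). The fry adjusted p, which ran from 0.0111 to 0.0861 over the scalings, filters, weights and left-out libraries, lay above 0.05 without 7 of the 9 libraries in fits added after the data were seen, namely Model replicate 1 (0.0614), 4 (0.0538) or 5 (0.0515), PH replicate 4 (0.0861), or PPH replicate 2 (0.0501), 3 (0.0779) or 4 (0.0616). It did so also with median-ratio scaling (0.0769), quantile normalization (0.0505) and library weights (0.0786), and furthest with a replicate block (0.168), outside the range above. All members stayed higher in PPH in each of these fits. Skeletal muscle genes, markers of soft tissue beside the bone, moved the same way in 2 comparisons, at a median of 0.76 in PPH against PH and -1.06 in PH against Model, where the fibrous list lay at 0.58 and -0.29. Both comparisons hold the same 3 PH libraries with opposite sign, so the 2 are not separate observations. In PPH against Model the 2 lists parted, muscle at -0.38 (0.09 without Model replicate 5) and fibrous at 0.27.

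**Figure D4:**
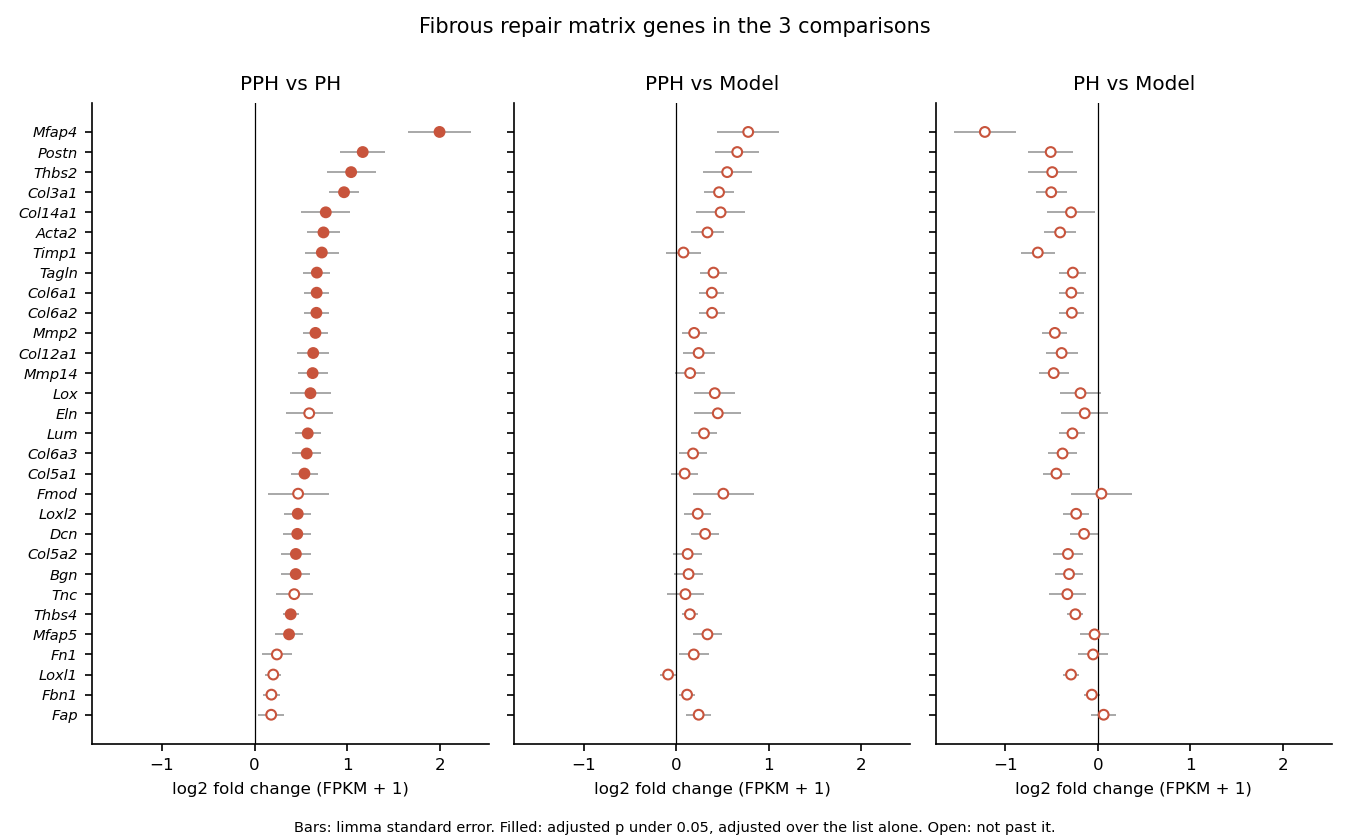
Log2 fold change (horizontal axis, on the FPKM + 1 scale) of the 30 fibrous repair matrix genes in PPH against PH, PPH against Model and PH against Model, with bars for the limma standard error; filled points passed adjusted p 0.05 over the list alone. All 30 points lie above 0 in PPH against PH, with 23 filled, and 0 are filled in the other comparisons.

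Bone and stromal lists were higher in PPH than in PH by camera. The library score was the median over members of the log2 difference from the Model mean. For osteoblast genes it was -0.237 in PPH replicate 2, within the PH range (-0.431 to -0.209). PPH replicate 2 lay within the PH range also for osteocyte, osteoclast, Wnt, BMP, endothelial and interferon genes, and above it for growth factor genes. PPH replicates 3 and 4 lay above the PH range, except replicate 4 for interferon genes. Osteoblast genes were higher in 22 of 22 cases (median log2 difference 0.36, camera adjusted p = 8.52e-10, but 0.359 with an estimated correlation), and 1 of them, Cthrc1, a collagen triple helix protein (log2 fold change 0.91), rose when adjusted over the list alone. Osteocyte genes were higher in 10 of 12 cases (median 0.31, camera adjusted p = 0.00041, estimated-correlation adjusted p = 0.359, 0 past limma over the list alone), with Ackr3 at 0.45 and the Wnt inhibitor Sost at -0.38. Osteoclast genes were higher in 14 of 16 (median 0.22, camera adjusted p = 0.000662, estimated-correlation adjusted p = 0.405), of which the proton pump subunit Tcirg1 (0.43) and the exchanger Slc9b2 (0.57) rose over the list alone. Adjusted over the list alone, 6 of 34 Wnt genes rose (median of the list 0.19), led by Rspo3 (0.51), Wnt16 (0.88) and Sfrp2 (0.71), and 5 of 24 growth factor genes (0.27), led by Ptn (0.52) and Pdgfrb (0.40). Of 31 BMP and TGF-beta genes (0.17) 1 rose, Tgfb3 (1.09), and 0 of 25 endothelial (0.18) and 0 of 27 interferon genes (0.20). Camera called these 5 lists at adjusted p of 7.8e-05, 2.88e-05, 0.000241, 7.8e-05 and 0.00725, in the order named. With an estimated correlation the adjusted p = 0.359 for the Wnt, growth factor, BMP and endothelial lists and 0.48 for interferon. With a score of marrow genes as a covariate the mean log2 difference went from 0.406 to -0.0097 for osteoblast, 0.243 to 0.0421 for osteocyte, 0.231 to -0.0604 for osteoclast and 0.186 to 0.0203 for endothelial genes. The interferon call ended without PH replicate 2 (median 0.14) or PPH replicate 3 (0.11). The other calls held, but without PPH replicate 3 the median was 0.20 for osteoblast, 0.18 for osteocyte, 0.11 for Wnt, 0.10 for BMP and 0.12 for endothelial genes. Without PPH replicate 2 it was 0.55 for osteoblast, 0.40 for osteoclast and 0.29 for endothelial genes, and without PH replicate 4 it was 0.10 for BMP genes.

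Skeletal muscle genes, markers of a neighbouring tissue, were higher in PPH than in PH as well, in 17 of 21 cases (median log2 difference 0.76, camera adjusted p = 5.44e-07). Of them 6 rose adjusted over the list alone, among them Acta1, the actin of muscle fibres (1.93 ± 0.51 SE), and Myl1, a myosin light chain (1.47 ± 0.46), and adjusted p = 0.359 with an estimated correlation. Blood and marrow lists were lower. Erythroid genes were lower in 26 of 26 cases (median -0.43, camera adjusted p = 5.94e-10, but 0.359 with an estimated correlation), and 9 fell adjusted over the list alone, among them Slc25a37 (-0.57), Rhag (-0.54) and Slc4a1 (-0.54). Proliferation genes were lower in 32 of 32 (median -0.30, adjusted p = 1.57e-11), with Kif23 at -0.37 and Mcm2 at -0.39, and adipocyte genes in 17 of 17 (median -0.37, adjusted p = 4.28e-06), with Fabp4 at -0.68; 0 of either list passed limma over the list alone. For proliferation and adipocyte genes the adjusted p = 0.359 with an estimated correlation. Neutrophil genes were lower in 21 of 22 cases (median -0.46, camera adjusted p = 2.88e-05, and adjusted p = 0.48 with an estimated correlation), with Lcn2 at -1.11. Their library score in PPH replicate 2 (0.551) lay among those of the PH libraries (0.15 to 0.716), and their median was -0.755 without PPH replicate 2 and -0.21 without PPH replicate 3. The median was -0.19 for proliferation genes without PPH replicate 3, -0.26 for erythroid genes without PH replicate 4 and -0.56 for adipocyte genes without PPH replicate 4, and these calls held.

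Macrophage genes were lower in PPH than in PH in 14 of 19 cases (median -0.21, camera adjusted p = 0.0261, and adjusted p = 0.405 with an estimated correlation). Cd163 and the complement gene C1qc (log2 fold change -0.47) fell when adjusted over the list alone. T and NK cell genes were lower in 21 of 23 cases (median -0.23, camera adjusted p = 0.00586, estimated-correlation adjusted p = 0.543). Megakaryocyte genes were lower in 14 of 14 (median -0.27, camera adjusted p = 0.0267, estimated-correlation adjusted p = 0.755), but their library score in PPH replicate 2 (0.816) lay above those of the PH libraries (0.0332, 0.541 and 0.689). The macrophage call ended without PH replicate 3 (median -0.19) or PPH replicate 2 (-0.26), and the T cell call without PPH replicate 2 (-0.24) or 3 (-0.08). The megakaryocyte call ended without PH replicate 3 (-0.23) or 4 (-0.15), or PPH replicate 3 (-0.06) or 4 (-0.16). Where the call held, the median was -0.09 for macrophage genes without PPH replicate 3, -0.35 for T cell genes without PPH replicate 4, and -0.46 and -0.60 for megakaryocyte genes without PH replicate 2 and PPH replicate 2. Cytokine genes were not called by camera, but Ccl3 (-0.66) and Ccl5 (-0.79) fell over the list alone (limma). The mixed test of fry, which asks whether members move in either direction, called 4 lists, namely cytokine and macrophage (adjusted p = 0.0318 each), Wnt (0.0309) and fibrous repair matrix (0.00528). The remaining lists not called by camera were hypoxia (median 0.05), cartilage (-0.24), B cell (-0.20), oxidative stress (-0.08), immediate-early (-0.05) and respiratory chain genes (0.00), and 3 whose median and mean differ in sign. These 3 were nerve (0.03 and -0.09), iron handling (0.02 and -0.02) and the ribosomal list (-8.5e-05 and 0.01), which lay at 0.00711 and 0.0216 without the S6 kinases and Rps19bp1. The B cell list was called lower without Model replicate 1, 4 or 5 (median -0.20 each), PH replicate 4 (-0.37) or PPH replicate 4 (-0.43). Cartilage genes were called without PH replicate 2 (-0.37) and respiratory chain genes without PH replicate 4 (0.05).

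For the bone genes chosen in advance, 12 of 14 were higher in PPH than in PH and 0 passed limma, either over all genes or adjusted over these 14 alone; 7 had an unadjusted p under 0.05. Spp1 (osteopontin, log2 fold change 0.69 ± 0.23 SE), Acp5 (0.67 ± 0.25), Ctsk (0.59 ± 0.24), Sp7 (0.49 ± 0.20), Col1a1 (0.46 ± 0.19) and Runx2 (0.31 ± 0.12) were the 6 higher ones of these, and Sost (-0.38 ± 0.16) the lower one. The smallest limma adjusted p over all genes was 0.239, for Spp1. For Runx2, Sp7, Col1a1, Spp1 and Sost an exact two-sided permutation test of 3 against 3 libraries gave p = 0.2, and for Acp5 and Ctsk p = 0.3, where the smallest possible value is 0.1.

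PH was set against Model to ask what differs with the peptide gel alone, and 0 genes passed limma over 12424 genes. Here too a batch that follows the groups cannot be told apart from the gel. The same 3 PH libraries stand in PPH against PH with the opposite sign. List changes of opposite sign in these 2 comparisons are therefore not separate observations. In PH against Model the smallest adjusted p was 0.166, for Pcyt1b, which stood at an FPKM of 2.48 ± 0.739 in PH and 0.39 ± 0.0701 in Model (SD, n = 3 each, limma log2 fold change 1.31 ± 0.17 SE). Bex4 (0.59), Fmo2 (0.61), Guk1 (a guanylate kinase, 0.33) and Cd163 (0.49) were the next higher ones. Tff3 (-0.72), the muscle genes Acta1 (-2.87) and Atp2a1 (-1.64), Sprn (-0.85) and Nicn1 (-0.40) were the lower ones with the smallest p. At an unadjusted p under 0.05 limma counted 384 genes higher and 401 lower, 785 in all against 621 expected if no gene differed. The count was 4 without Model replicate 1 or PH replicate 4, and 1 without Model replicate 4 or PH replicate 3.

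Skeletal muscle genes fell furthest between PH and Model. They were lower in PH in 19 of 21 cases (median log2 difference -1.06, camera adjusted p = 3.13e-16, and adjusted p = 0.456 with an estimated correlation), and 14 fell adjusted over the list alone, 0 over all genes. Acta1 stood at 2.32 ± 1.70 FPKM in PH and 26.4 ± 22.3 in Model (SD, n = 3 each), and in Model replicate 5 alone it stood at 52.1. Tnnc2 (log2 fold change -2.02 ± 0.47 SE) and the creatine kinase gene Ckm (-2.10 ± 0.49) were also among the 14. Fibrous repair matrix genes were lower in 28 of 30 cases (median -0.29, camera adjusted p = 5.88e-14, and adjusted p = 0.366 with an estimated correlation), led by Mfap4 (-1.22) and Timp1 (-0.65), with 0 past limma over the list alone. Osteoblast genes were lower in 20 of 22 (median -0.30, adjusted p = 2.6e-09) and osteoclast genes in 13 of 16 (median -0.24, adjusted p = 3.71e-05), again with 0 past limma over either list, and for both adjusted p = 0.456 with an estimated correlation. Growth factor (19 of 24 lower, median -0.18), endothelium (18 of 25, -0.10), Wnt (25 of 34, -0.10), BMP and TGF-beta (21 of 31, -0.08) and osteocyte genes (10 of 12, -0.20) were called lower at camera adjusted p of 0.000197 to 0.0181. For these 5 lists adjusted p = 0.456 with an estimated correlation. Calls held while the median was -0.16 for osteoclast and -0.115 for growth factor genes without Model replicate 4, and -0.13 for osteoclast, -0.115 for growth factor, -0.06 for Wnt and -0.04 for BMP genes without PH replicate 4. For BMP genes it was -0.13 without Model replicate 5 and -0.12 without PH replicate 3.

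Marrow and blood lists were higher in PH than in Model by camera. Erythroid (26 of 26 higher, median log2 difference 0.32, camera adjusted p = 1.11e-08), proliferation (32 of 32, 0.17, adjusted p = 3.38e-07) and neutrophil genes (22 of 22, 0.40, adjusted p = 1.28e-05) were higher in all members, but for each the adjusted p = 0.456 with an estimated correlation. Megakaryocyte (14 of 14, 0.45, adjusted p = 1.28e-05), adipocyte (16 of 17, 0.31, adjusted p = 7.86e-06) and the ribosomal list (89 of 101, 0.09, adjusted p = 1.05e-05) were called too, with 0.456, 0.456 and 0.545 when the correlation was estimated. Without the S6 kinases and Rps19bp1 the ribosomal list had 83 of 92 genes higher (median 0.09, camera adjusted p = 5.62e-06, estimated-correlation adjusted p = 0.533). Macrophage genes (14 of 19, 0.17, adjusted p = 0.00994) and oxidative stress genes (19 of 23, 0.10, adjusted p = 0.0262) completed the 8, both at 0.456 with an estimated correlation. Cd163 (0.49) alone rose adjusted over its list, and in the other 7 lists 0 members passed limma. In PH against Model fry called 0 of the 27 lists (lowest adjusted p = 0.442). The osteocyte, BMP and Wnt calls ended without Model replicate 4 (medians -0.15, -0.04 and -0.05) or PH replicate 2 (-0.145, -0.06 and -0.08). The endothelium call ended without Model replicate 4 (-0.06) and the oxidative stress call without Model replicate 1 (0.11) or PH replicate 4 (0.08). Without PH replicate 4 the median was 0.15 for erythroid, 0.24 for neutrophil and 0.11 for proliferation genes, and these calls held. So did those for erythroid genes without PH replicate 2 (0.49), adipocyte genes without Model replicate 1 (0.19), macrophage genes without Model replicate 5 (0.26) and the ribosomal list without Model replicate 4 (0.06). The other 10 lists were not called by camera. They were cartilage (median 0.14), T and NK cell (0.15), B cell (-0.07), nerve (0.03), interferon (-0.05) and respiratory chain genes (0.04), and 4 whose median and mean differ in sign. These were iron and metal handling (-0.01 and 0.04), hypoxia (0.04 and -0.01), cytokine (-0.03 and 0.01) and immediate-early genes (0.03 and -0.000147). Of these, cartilage was called without PH replicate 2 (0.27) or Model replicate 5 (0.25), B cell without PH replicate 2 (-0.31) or Model replicate 4 (-0.17), and T and NK cell genes without Model replicate 1 (0.18) or 4 (0.13). Interferon genes were called without Model replicate 1 (-0.11) or 5 (-0.12) or PH replicate 4 (-0.11), and immediate-early (-0.04) and respiratory chain genes (0.06) without PH replicate 3.

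Of the 14 bone genes, 3 were higher and 11 lower in PH than in Model, 4 at an unadjusted limma p under 0.05 and 0 past adjustment. These 4 were Sost (log2 fold change 0.55 ± 0.16 SE), Col1a1 (-0.49 ± 0.19), Acp5 (-0.62 ± 0.25) and Spp1 (-0.55 ± 0.23), and each separated the 3 libraries of a group from those of the other. With quantile normalization, which gives every library the same value at the same rank, the Col1a1 difference was 0.00. A gene that keeps its rank gets 0 there whatever its FPKM, so this value does not bear on the difference. Ibsp (0.01) and Vegfa (0.04), among the 3 higher genes, were lower with equal sums (-0.06 and -0.03).

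The fold changes of PPH and of PH against Model, which share the Model libraries, had a Pearson correlation of 0.0996 across genes, which are not independent replicates. Unchanged groups simulated against a shared control gave a median of 0.472, with 8 of 100 draws at or below the observed value. That control was drawn from the deviations of all 9 libraries from their group means, not from Model alone. The simulation therefore does not hold Model's own spread, and cannot say whether the observed value is low for groups that share Model. The covariance was 0.00312, against 0.0112 in the simulation, where 14 of 100 draws lay at or below it. The correlation was -0.127 without PPH replicate 2 and 0.351 without PPH replicate 3, and 3 Model libraries are too few to split between the comparisons. Muscle genes were lower against Model in both groups (medians -1.06 in PH and -0.38 in PPH), but without Model replicate 5, which both comparisons share, the PPH median was 0.09. Fibrous repair matrix genes were lower in PH (-0.29) and higher in PPH (0.27).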

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

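Leaving out the intestinal genes, the ribosomal list without S6 kinases and Rps19bp1 (which changed no list call), and the fry tests of the fibrous list under other settings, were chosen only after the result was seen. No named gene past the threshold changed sign, but bone genes short of it did, such as Bglap (-0.0894), Acp5 (-0.0694) and Col1a1 (0.155) in PPH against Model with quantile normalization. Lists reversed only in PPH against Model, 10 times. The cause was not tested. In PPH against Model the 1 gene became 2 with a pseudocount of 0.01, with no filter and with only the 2 groups compared (0 shared), 0 with the intestinal genes left out, and 0 to 3 without single libraries. Its 15 lists became 8 with library weights, 7 to 20 without single libraries, and 0 with camera at an estimated correlation and 0 with fry. In PPH against PH the 5 genes became 3 at a mean of 5 FPKM, where fewer genes were tested, 20 with equal sums (19 higher, 1 lower), 2 with library weights, 9 with only the 2 groups (3 shared), 0 without the intestinal genes, and 1 to 1004 without single libraries. All genes called in these 2 comparisons belong to the list of intestinal genes, so leaving it out had to remove them and says nothing of how stable they are. Its 17 lists became 0 with an estimated correlation and 1 with fry, and 14 to 18 without single libraries. In PH against Model the 0 genes (785 at an unadjusted p under 0.05, limma) became 1 with a pseudocount of 0.1 or 0.01 and with library weights, and 0 to 4 without single libraries. Its 17 lists became 0 with an estimated correlation and 0 with fry. The robust and untrended fits cannot move list tests.

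Of single lists in PPH against Model, the median (log2) without single libraries ran from -0.148 (without PPH replicate 3) to 0.261 for osteoblast, 0.00642 to 0.242 for osteocyte, 0.0209 to 0.131 for BMP and TGF-beta, -0.000144 to 0.155 for growth factor, 0.00588 to 0.13 for endothelium and 0.0266 to 0.265 for interferon genes, and camera's direction turned without PPH replicate 3 in these 6 lists (endothelium 0.00683). It ran from -0.251 to 0.0539 (without PPH replicate 4) for cartilage, -0.259 to -0.0115 (without PPH replicate 4) for erythroid, -0.177 (without PPH replicate 2) to 0.355 for megakaryocyte and -0.601 to 0.0901 (without Model replicate 5) for muscle genes, and turned without the library named. Where a library is left out, its group holds 2, and fewer samples alone lower the power of the test.

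With a replicate block in PPH against PH, 8 genes were called (1 shared with the 5) and 18 lists by camera, and the fry adjusted p of the fibrous list was 0.168, above the threshold it had passed without the block (0.0219). The labels do not say whether a shared number marks a pair. Deviations of same-numbered PPH and PH libraries correlated across genes, which are not independent replicates, at -0.149, 0.264 and -0.246. With 3 libraries per group these values cannot exclude a pairing. Not every library correlated best with its own number. Depth per library is known only relative to Model replicate 1, so the counting error of low genes cannot be given.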

Other observations

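The eosinophil and mast cell list, the MHC class I list, the tests on intestinal genes, the osteoblast test with a marrow score, the scaling test and the muscle tests were chosen only after the result was seen; the splits and the fibrous test with a marrow score were set in advance.

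Genes of eosinophils and mast cells, granulocytes of allergic and tissue responses, were higher in PH than in Model in 17 of 18 cases (median log2 difference 0.59), and 7 rose adjusted over the list alone. Fcer1a, the IgE receptor chain (0.74 ± 0.17 SE), Ccr3, the eotaxin receptor (0.50 ± 0.13), and the mast cell proteases Tpsb2 (1.22 ± 0.40) and Mcpt10 (0.89 ± 0.29) were among them. In PPH against PH the list lay at -0.70, where Ccr3 (-0.58), Siglec5 (-0.88) and Alox15 (-0.71) fell adjusted over the list alone. The list was written after values were seen, so these counts are no independent evidence.

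In a list of MHC class I genes and Fam111a, Fam111a was higher in each PPH library than in any PH library (log2 fold change 3.15 ± 0.68 SE, limma adjusted p = 0.131 over all genes), and differed among the Model libraries. It lay at 225.4 to 424 FPKM in the PPH libraries, 29.6 to 40.5 in the PH libraries and 240.1, 25.4 and 225.2 in Model replicates 1, 4 and 5. RT1-CE16 stood at 81.8 in PH replicate 3 and 140.2 in PPH replicate 3, against 0.154 to 1.18 in the Model libraries. RT1-A2 stood at 7.26 FPKM in PPH replicate 4. The list was put together after these values were seen, so it is no independent evidence.

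Small intestine transcripts were higher in all 3 PPH libraries (log2 scores 0.393 to 0.497) than in the Model (-0.244 to 0.126) and PH libraries (-0.513 to -0.33). Reads of neutrophil defensins counted for Paneth cell defensins are argued against as the whole cause, since the intestinal genes other than defensins differed by 0.915 ± 0.0762 (SE) between PPH and PH while the neutrophil defensin Np4 lay at -0.442. One intestinal source mixed in at different amounts would keep a fixed FPKM ratio of enterocyte to goblet and Paneth transcripts. On the log2(FPKM + 1) scale used, low genes move less, so the ratio need not stay fixed even then. It differed by up to 0.914 ± 0.238 between Model replicate 4 and PH replicate 4 with Model replicate 1 left out. These were the highest and lowest libraries left, a choice the SE does not count, so the test did not decide whether there was one source. Intestinal RNA that entered group by group during handling or sequencing may account for the difference of 0.894 ± 0.0642, and cannot be told apart from the treatment, because the labels give no batch. The records of the PH samples are numbered apart from those of Model and PPH, which does not show whether PH was handled apart. A biological difference from the treatment stays open and untested.

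Fibrous repair matrix transcripts were higher in PPH than in PH by 0.617 ± 0.103 (mean log2, SE), and by 0.555 ± 0.146 with a score of marrow genes as a covariate, which argues against a lower share of marrow cells as the whole cause. Globin and other abundant transcripts taking another share of the total are argued against too, since median-ratio scaling gave a median of 0.595 against 0.582. For osteoblast genes the marrow score took the difference from 0.406 ± 0.188 to -0.0097 ± 0.0366, so a lower share of marrow cells in the PPH libraries is a candidate explanation there. The marrow score was 0.16, -0.389 and -0.018 in PPH replicates 2, 3 and 4, and 0.173, 0.192 and 0.323 in PH replicates 2, 3 and 4. The covariate cannot tell a lower marrow share from a higher bone share, because FPKM is a relative unit. More muscle left on the bone with the tissue around it is argued against as the whole cause of the fibrous difference, which was 0.668 ± 0.129 with a muscle score as a covariate and 0.699 ± 0.2 without Model replicate 5. Soft tissue without muscle was not tested, and an effect of the treatment on repair tissue or on marrow stays open as a hypothesis. Handling of the groups apart from each other could not be tested for these lists either, because the labels give no batch.

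Skeletal muscle transcripts were lower in PH than in Model by -1.12 (log2, difference of library medians). Different amounts of muscle left on the bone may account for this, since the Model libraries alone spanned 1.42, but they spanned 0.129 without Model replicate 5, where 20 of 21 muscle genes were highest, so 1 library keeps this open. Without Model replicate 5 the list was still called lower by camera at the preset correlation, and its median ran from -1.36 to -0.848 over the libraries left out. With all libraries and an estimated correlation camera gave an adjusted p of 0.456. No biological explanation was tested.

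The libraries of a comparison can be split in 10 ways, too few for a share under 0.05. The real groups are counted among the splits below. In PPH against Model, 1 of 10 splits gave as many genes (1, highest other 0) and 6 as many lists (15, highest other 19); genes at an unadjusted limma p under 0.05 numbered 409 (highest other 1294). In PPH against PH, 2 gave as many genes (5, highest other 7), 3 as many lists (17, highest other 18) and 1 as large a fibrous median (0.582, highest other 0.391), with 1947 genes at an unadjusted limma p under 0.05 (highest other 1891). In PH against Model, 10 gave as many genes (0, highest other 1) and 2 as many lists (17, highest other 17), with 785 at an unadjusted limma p under 0.05 (highest other 428). Over all 9 libraries 100 splits were fitted, the real groups among them. Of these, 15 gave at least as many genes at an unadjusted F-test p under 0.05 as the real groups (1149, highest other 2262). Chance was therefore not excluded. At an adjusted p, 18 of the 100 gave as many (1, highest other 35), and whether the split with 35 follows a structure of the libraries was not tested.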
